A study of Mus musculus with 6 samples.

How the data were processed

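The series holds 6 RNA sequencing libraries of the mouse melanoma line B16, 3 treated with DMSO and 3 with 1 uM CX-5461 for 3 days, and groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, cells were grown in DMEM with serum and antibiotics, total RNA was taken and a column kit was used for the extraction. The deposited table gives whole-number counts of reads per gene for 22740 protein-coding genes with Ensembl identifiers, symbols and coordinates, and these counts had not been normalized by the authors, as shown by column totals that differ. The builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting tool, its annotation, whether strand was used and how multiply mapped reads were treated are not given in the sources used here. Reads shared by near-identical genes, or by genes that overlap on opposite strands, can therefore not be assigned with certainty. Genes of other biotypes, such as ribosomal RNA, were not analysed here. All 6 columns were mapped to samples by name.

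Library totals ran from 17573990 to 22908309 counts, and 3 counts, the floor used for a gene with no count, equalled 0.135 to 0.173 CPM. This floor covers counting error only. Genes were kept by filterByExpr of edgeR 4.0.16 with its default minimum count of 10, which left 12198 genes that held at least 99.95% of the counts of each library. TMM factors ran from 0.970 to 1.03. The test was edgeR's quasi-likelihood F test (R 4.3.3), with an intercept and the treatment as the model, two-sided, on all 6 libraries. Benjamini-Hochberg adjustment was applied over all tested genes and an adjusted p below 0.05 was called a change. Log2 changes are CX-5461 minus DMSO, their standard errors were taken as the change divided by the square root of F, and CPM were scaled to library totals times their TMM factors. The common biological coefficient of variation was 4.86%. Every adjusted p of a gene in the text is from this test unless another is named.

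Before the data were examined, 29 gene lists and the rule for named genes were fixed. The lists were those of the report, 12 of them core lists, with 727 memberships tested, 150 left out for low counts and 4 symbols not found in the table under the names used (Ptprv, Ifit3b, Msmo1 and Adgre1). The rule took the 6 largest rises and the 6 largest falls among genes with a called change, a mean of at least 5 CPM in the higher group, libraries of the groups that did not overlap, and a symbol that is not a clone, predicted-gene or pseudogene name. It added the 3 called members with the largest change from each core list and 1 from each other list, again at 5 CPM or more, or the most abundant member where no member met this. It always named Mitf, Tyr, Tyrp1, Dct, Trp53, Cdkn1a, Mdm2, Polr1a, Rrn3, Ubtf, Myc, Mki67, Top2a and Top2b. A gene that the rule took from the list of the BCL2 family and caspases is not reported here. Lists with at least 3 tested members, 27 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were alternatives. Counts of changed members were also adjusted over the list alone, and for 25 of the 29 lists these equalled the counts over all genes. Further lists of NRF2 targets, the heat shock response, quiescence and FOXO targets, glucose-induced MondoA targets, the 26S proteasome, the cytosolic chaperonin, collagens, axon guidance and olfactory receptors were chosen after the main results had been seen.

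The reference annotation used here is of build GRCm38, the build of the deposited table, and 21919 of the 22740 identifiers matched it. Printed gene coordinates, gene spans, exonic lengths and GC content come from this annotation, and 99.5% of the tested genes had a GC value. The tests were checked on simulated counts of 12112 genes, with each gene's mean over all 6 libraries and with the library sizes of the data. Only the few genes counted next were changed, whereas 73.67% of the tested genes were called in the data. The check therefore does not cover so broad a change. The edgeR test recovered 34 of 50 genes changed 1.25-fold, 40 of 50 at 1.5-fold, 45 of 50 at 2-fold and 50 of 50 at 4-fold, and 29 of 30 members of a simulated list raised 2-fold. Of its 216 calls, the other 18 were false. Alternatives fixed in advance were RLE and upper-quartile factors, library totals only, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a GC offset with and without that block, removal of the 50 most abundant and the mitochondrial genes, an adjusted p of 0.01, each library left out in turn, and counts thinned to the smallest library. An offset for the genomic span of each gene was added after seeing the data. The offsets were lowess curves of span 0.4 per library.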

Results

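RNA was measured by sequencing in B16 cells, a mouse melanoma line that makes melanin, after 3 days with the vehicle DMSO or with 1 uM CX-5461. CX-5461 is a small molecule known as an inhibitor of transcription by RNA polymerase I, the enzyme that copies the ribosomal RNA genes. Each group had 3 samples, numbered as replicates 1 to 3, and each library was described by 1 deposited count per protein-coding gene. The libraries held 17573990 to 20198979 counts in the DMSO group and 17877481 to 22908309 in the CX-5461 group. Between 13895 and 14000 genes had a count in each DMSO library, and between 14420 and 14831 in each CX-5461 library. The mitochondrially encoded genes took 1.70% to 1.84% of the counts in the DMSO libraries and 2.70% to 3.40% in the CX-5461 libraries. In every library the gene with most counts was mt-Co1, a subunit of cytochrome c oxidase. The first principal component of log2 CPM held 91.2% of the variance and parted the groups. Replicates of a group were never alike to within sampling noise, with a chi-square per degree of freedom of 1.57 to 2.54 between DMSO libraries and of 5.65 to 9.39 between CX-5461 libraries. Of the latter, 9.39 and 7.64 came from the pairs with CX-5461 replicate 2. That library also lay apart on the second principal component (2.83% of the variance), at -15.6 against 8.49 and 6.91 for CX-5461 replicates 1 and 3.

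The comparison asks how the transcripts of these melanoma cells differed after CX-5461, in a study concerned with sorting melanoma cells by how much pigment they hold. With CX-5461 the genes of DNA replication, mitosis, pigmentation and the p53 response were mostly higher, and those of the ATF4 stress response, ribosome assembly and hypoxia were mostly lower. Mitf, the master regulator of the melanocyte lineage, rose from 96.3 ± 3.20 to 435.8 ± 12.1 CPM (SD, n = 3 per group), which was 4.53-fold, or 2.80-fold with an offset for the genomic span of genes that was chosen after seeing the data. Cdc6, which loads the replicative helicase, rose 11.7-fold, from 3.66 ± 0.521 to 43.0 ± 4.68 CPM. Cdkn1a, the cell-cycle inhibitor induced by p53, rose 2.44-fold, from 413.3 ± 13.7 to 1009.7 ± 26.2 CPM. Ppp1r15a, a phosphatase subunit of the integrated stress response, fell 8.64-fold, from 485.0 ± 31.8 to 56.2 ± 2.62 CPM.

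Of 12198 genes tested, 4538 were higher and 4448 lower with CX-5461 at an adjusted p below 0.05, and 3212 did not pass (edgeR quasi-likelihood test). At least 2-fold, 1430 genes were higher and 508 lower. All 3 libraries of one group lay beyond all 3 of the other for 9289 genes, or 76.2%, where chance gives 10%. The median log2 change of all tested genes was -0.005, which TMM scaling holds near 0, so only changes relative to other genes can be seen. With library totals only it was -0.0785, with 3989 genes higher and 5109 lower. The 6 genes with the largest rises among those named by the fixed rule were Ces2e, Lgr6, Serpine2, Dgki, C1s and Cpz. Ces2e, a carboxylesterase on chromosome 8 (104926260 to 104934672, GRCm38), had no count in any DMSO library and 5.65 ± 0.879 CPM with CX-5461. It was therefore at least 33.7-fold higher, against a floor of 3 counts in the shallowest DMSO library. Lgr6, a receptor for R-spondins on chromosome 1 (134983301 to 135105276), rose by 5.53 ± 0.24 (log2, SE), and Serpine2, a secreted protease inhibitor, by 4.83 ± 0.13. Dgki, a diacylglycerol kinase, rose by 4.78 ± 0.13, C1s, a complement protease, by 4.77 ± 0.11, and Cpz, a carboxypeptidase, by 4.63 ± 0.14. The 6 with the largest falls were Sh2d6, Cdsn, Akr1b7, Angptl6, Pdzd7 and Ppp1r15a. Sh2d6 on chromosome 6 (72513641 to 72521707) changed by -4.58 ± 0.15, Cdsn, which encodes corneodesmosin, by -4.36 ± 0.15, and Akr1b7, an aldose reductase relative, by -4.32 ± 0.13. Angptl6, an angiopoietin-like secreted protein, changed by -3.48 ± 0.07 and Pdzd7 by -3.15 ± 0.13. Ces2e, C1s and Akr1b7 have close relatives in the mouse genome with which reads can be shared, so their values are uncertain. Genes that span 200 to 400 kb, among them Mitf, Oca2, Pola1, Gfra1 and Uvrag, had a median log2 change of 0.97, and those over 400 kb, among them Dgki, a median of 1.71. With the gene-span offset Dgki rose 11.7-fold in place of 27.5-fold.

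Of 28 genes of melanin synthesis and the melanosome, 23 rose, 2 fell and 3 did not pass, with a median log2 change of 0.51. The melanosome transport adaptor Mlph rose 5.12-fold, the melanosomal transporter Oca2 5.05-fold (2.65-fold with the gene-span offset) and the melanosomal receptor Gpr143 3.19-fold. The enzymes of melanin synthesis rose as well. Tyr, tyrosinase, rose by 1.05 ± 0.06 (log2, SE, n = 3 per group), Tyrp1 by 0.56 ± 0.05 and Dct by 0.36 ± 0.05, the latter from 8576 ± 54.2 to 11013 ± 491.7 CPM. The list passed the camera set test (adjusted p = 2.106e-07), with adjusted p = 0.323 with an estimated correlation. Of 11 melanocyte lineage regulators tested, 9 rose, none fell and 2 did not pass, with a median of 1.00. Kit, the receptor of stem cell factor, rose 9.94-fold, Mitf (chromosome 6, 97807052 to 98021349) 4.53-fold (2.80-fold with the gene-span offset) and Mc1r, the melanocortin receptor, 3.87-fold. This list passed as well (camera, adjusted p = 3.81e-09), with adjusted p = 0.2033 with an estimated correlation. The 15 tested markers of undifferentiated and invasive melanoma went both ways, with 6 higher, 6 lower and 3 not passed. Ngfr, a neural crest receptor, rose by 2.15 ± 0.17, and Pdgfrb and Itga5 changed by -1.28 ± 0.12 and -1.10 ± 0.05. For this list the median was 0.07 and the mean 0.13, whereas camera gave the lower direction (adjusted p = 0.8225). Camera compares a list with the other genes, so its direction need not be the sign of the list's own median or mean. Without CX-5461 replicate 2 the direction of that test turned, with a median of 0.01 and adjusted p between 0.7257 and 0.9042 over all alternatives.

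**Figure D1:**
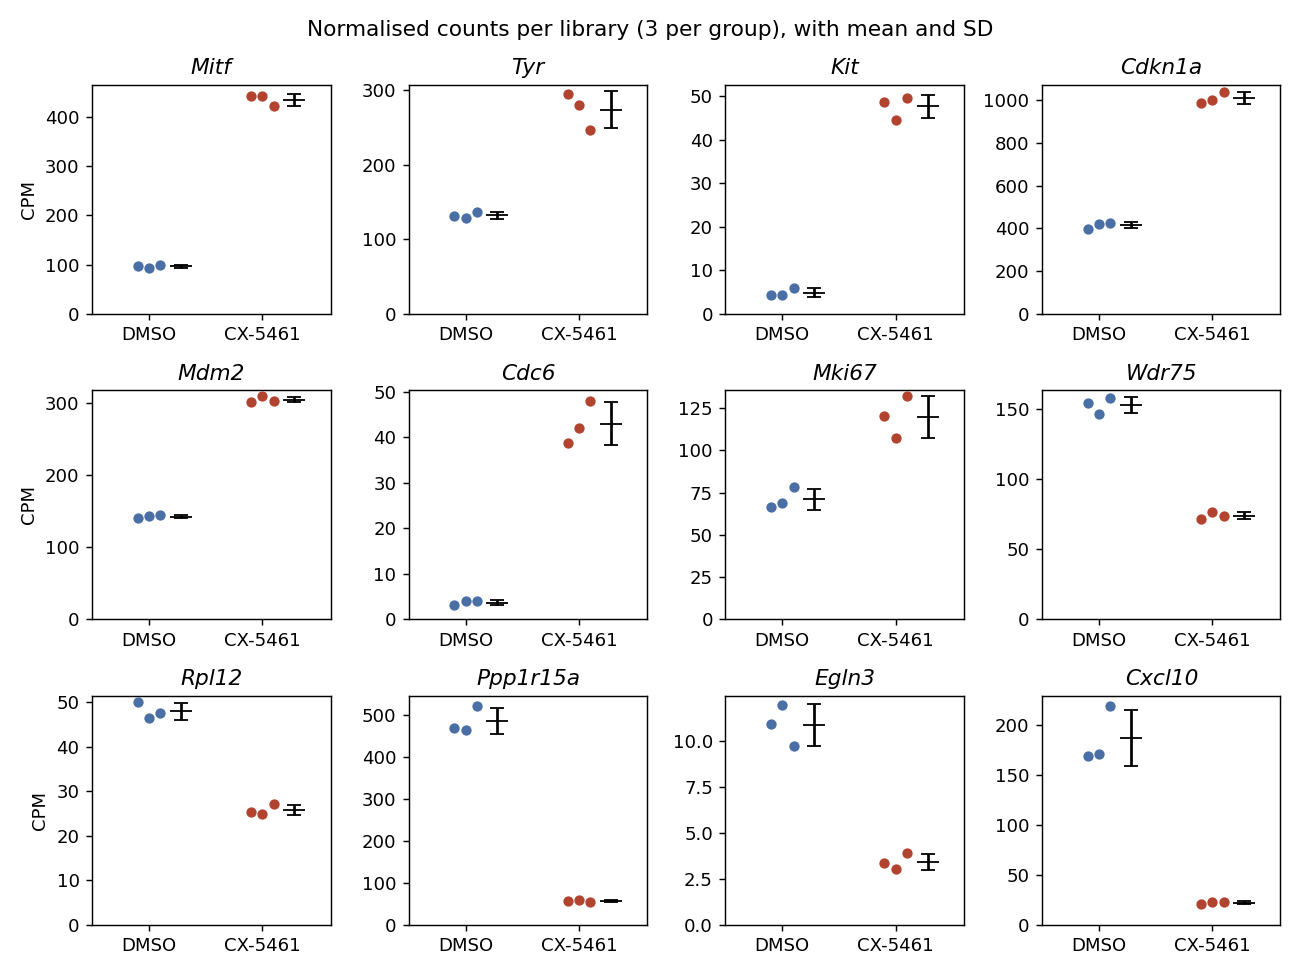
CPM (vertical axes, from 0) of 12 genes in the 3 DMSO libraries (blue points) and the 3 CX-5461 libraries (red points), with the mean and SD of each group in black. The libraries of the groups did not overlap for any of these genes, with Mitf at 96.3 against 435.8 CPM and Ppp1r15a at 485.0 against 56.2 CPM on average.

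Genes of the list of p53 targets were mostly higher. Of 34 p53 targets tested, 25 rose, 4 fell and 5 did not pass, with a median log2 change of 0.60. Ccnd1, which encodes cyclin D1 and is also set by growth signals, rose 16.8-fold, so its rise need not come from p53. The ectodysplasin receptor Eda2r rose 8.81-fold and the cyclin relative Ccng1 4.36-fold. Mdm2, the ubiquitin ligase of p53, rose by 1.10 ± 0.04, and Cdkn1a (chromosome 17, 29090976 to 29100727) by 1.29 ± 0.04. The transcript of p53 itself, Trp53, changed by -0.52 ± 0.05. Camera called the p53 list higher (adjusted p = 1.535e-09), with adjusted p = 0.2737 with an estimated correlation. Of 19 genes of the BCL2 family and caspases, 9 rose, 4 fell and 6 did not pass, and the list did not pass (adjusted p = 0.251).

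The genes of ribosome production were mostly lower, with medians between -0.39 and -0.23. Over alternatives the medians ran from -0.47 to -0.295 for biogenesis factors and from -0.35 to -0.17 for ribosomal protein genes. For the RNA polymerase I machinery they ran from -0.30 to -0.11. Among 15 genes of the RNA polymerase I machinery none rose, 9 fell and 6 did not pass, with a median of -0.23. Taf1a and Taf1b, subunits of the selectivity factor, changed by -0.89 ± 0.09 and -0.63 ± 0.07, and the polymerase subunit Twistnb by -0.72 ± 0.07. The initiation factor Rrn3 changed by -0.21 ± 0.05, with -0.29 to -0.11 over alternatives (adjusted p = 0.001589, with up to 0.04482 over alternatives). Ubtf, the upstream binding factor, was at 158.7 ± 1.12 CPM with DMSO and 155.2 ± 6.91 CPM with CX-5461 (adjusted p = 0.5281). With the gene-span offset it took the opposite sign and passed as higher, at 0.10 (adjusted p = 0.04672, with up to 0.9706 over alternatives). Polr1a, the catalytic subunit, was at 131.2 ± 4.79 and 140.6 ± 11.5 CPM (adjusted p = 0.1236), and passed without CX-5461 replicate 2, at 0.16 (adjusted p = 0.002285, with up to 0.6731 over alternatives). This list did not pass camera (adjusted p = 0.07174), though it did with no filter on low counts (adjusted p = 0.0413, with up to 0.1753 over alternatives). Of 48 ribosome biogenesis factors, 3 rose, 40 fell and 5 did not pass, with a median of -0.39. Wdr75 and Mphosph10, of the small-subunit processome, fell 2.07-fold and 1.99-fold, and the nucleolar protein gene Nop16 fell 2.01-fold. Camera called this list lower (adjusted p = 3.598e-06), with adjusted p = 0.2033 with an estimated correlation. Of 79 cytosolic ribosomal protein genes, 1 rose, 49 fell and 29 did not pass, with a median of -0.28. Rpl12, Rpl24 and Rpl10a changed by -0.90 ± 0.06, -0.76 ± 0.05 and -0.75 ± 0.05. Many ribosomal protein genes have processed copies that share their reads, so their levels are uncertain. The ribosomal protein list was also called lower (camera, adjusted p = 0.0008022), with adjusted p = 0.5628 with an estimated correlation. The 19 genes of the MYC network and its targets went both ways, with 7 higher, 9 lower and 3 not passed (camera, adjusted p = 0.8225). Their median was -0.07 and their mean 0.07, and camera gave the lower direction, which turned with the gene-span offset, where the median was 0.06. Myc was at 38.7 ± 1.57 and 41.1 ± 0.499 CPM (adjusted p = 0.1938), and passed with that offset at 0.20 (adjusted p = 0.006539, with up to 0.8458 over alternatives). The MYC antagonist Mxd3 rose by 1.93 ± 0.15.

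Genes of the cell cycle were higher with few exceptions. Of 49 genes of the G1/S transition and DNA replication, 48 rose and 1 did not pass, with a median 3.16-fold rise. Besides Cdc6 (chromosome 11, 98907801 to 98923940), thymidine kinase Tk1 rose 7.70-fold and the DNA polymerase subunit Pola1 6.59-fold, or 3.29-fold with the gene-span offset. Camera called the G1/S list higher (adjusted p = 5.496e-29), with adjusted p = 0.2737 with an estimated correlation. Of 45 genes of G2/M and mitosis, 43 rose and 2 did not pass, or 44 and 1 when adjusted over the list alone, with a median 2.03-fold rise. The kinetochore gene Nuf2 rose 3.30-fold, the chromokinesin Kif4 2.99-fold and the cytokinesis gene Anln 2.65-fold. Mki67, the proliferation marker, rose by 0.75 ± 0.07 and Top2a, topoisomerase II alpha, by 1.18 ± 0.08. Top2b, the other topoisomerase II, was at 107.9 ± 2.34 and 109.9 ± 8.08 CPM (adjusted p = 0.689). Its sign turned with library totals only (-0.05), with the gene-span offset (-0.004) and without CX-5461 replicate 2 (-0.04). With a GC offset Top2b was higher by 0.23 (adjusted p = 0.0009078, between 0.0002833 and 0.9576 over alternatives). The mitosis list passed camera (adjusted p = 9.813e-11), with adjusted p = 0.3752 with an estimated correlation. Of 33 genes of double-strand break repair and damage signalling, 26 rose, 5 fell and 2 did not pass, and 27 rose when adjusted over the list alone. Rad54l, of homologous recombination, rose 6.37-fold, and Fanci and Fancd2, of the Fanconi anaemia pathway, rose 5.65-fold and 5.00-fold. The repair list was called higher (camera, adjusted p = 5.181e-07), with adjusted p = 0.3531 with an estimated correlation. Of 67 replication-dependent histone genes only 11 had enough counts to be tested, of which 10 rose and 1 did not pass. Most of the histone list was therefore not measured, and the tested members need not stand for it. Hist1h2bc, which spans 8.71 kb where the tested members have a median of 2.31 kb, rose 6.25-fold. Whether the rise of these histone genes reflects DNA replication was not tested. This list passed camera (adjusted p = 0.01894), with adjusted p = 0.3752 with an estimated correlation. It did not pass without CX-5461 replicate 2 (adjusted p = 0.07886) or with no filter on low counts (0.2135), and the lowest over alternatives was 0.01071.

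Stress and metabolic genes moved in different directions. Of 28 genes of the integrated stress response driven by ATF4, 27 fell and 1 did not pass, with a median 1.97-fold fall. Ppp1r15a (chromosome 7, 45522916 to 45526268) changed by -3.11 ± 0.06. Among members chosen after their values were seen, Atf4 itself changed by -1.01 ± 0.04, Ddit3, which encodes CHOP, by -1.91 ± 0.06, and asparagine synthetase Asns by -1.41 ± 0.04. The list passed camera (adjusted p = 3.331e-29) and was the only one of 27 to pass with an estimated correlation (adjusted p = 0.02869). Of 20 genes of the unfolded protein response, 14 rose, 4 fell and 2 did not pass, with a median of 0.50. The chaperone cofactor Sdf2l1 rose 2.36-fold. The list passed camera (adjusted p = 0.0006657), with adjusted p = 0.3531 with an estimated correlation. Of 30 genes of cholesterol and fatty acid synthesis, 22 rose, 5 fell and 3 did not pass, and the sterol dehydrogenase gene Nsdhl rose 2.61-fold. That list passed camera (adjusted p = 0.01131), with adjusted p = 0.3752 with an estimated correlation. Of 30 genes of glycolysis and the hypoxia response, 5 rose, 19 fell and 6 did not pass, with a median of -0.45. Egln3, an oxygen sensor induced by hypoxia, fell 3.17-fold. The glycolysis and hypoxia list was called lower (camera, adjusted p = 0.000138), with adjusted p = 0.4445 with an estimated correlation. Of 61 nuclear genes of oxidative phosphorylation, 40 rose, 3 fell and 18 did not pass, with a median of 0.23. Cox6a1, a cytochrome c oxidase subunit, rose 1.73-fold. The list passed camera (adjusted p = 0.02904), with adjusted p = 0.8012 with an estimated correlation. Its call ended with a GC offset (adjusted p = 0.06395), with that offset and a replicate block (0.0657), and without CX-5461 replicate 2 (0.06459), and the lowest over alternatives was 0.000119. All 10 tested mitochondrially encoded genes rose, with a median of 0.99, and the mitochondrial share of counts was 2.70% to 3.40% in the CX-5461 libraries against 1.70% to 1.84%. Of these mt-Cytb rose 2.34-fold, to 7305 ± 784.9 CPM. Chosen after its values were seen, mt-Co2 held 0.986 ± 0.178 CPM with DMSO, where mt-Co1 held 9456 ± 314.2 CPM, so the levels of these genes also rest on how their reads were counted. The mitochondrially encoded genes passed camera (adjusted p = 0.004654), with adjusted p = 0.4447 with an estimated correlation. The 39 genes of the lysosome and autophagy had 17 higher, 14 lower and 8 not passed, and 18 higher when adjusted over the list alone. They did not pass (adjusted p = 0.4057), and Uvrag, of autophagosome maturation, rose 2.88-fold, or 1.62-fold with the gene-span offset.

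**Figure D2:**
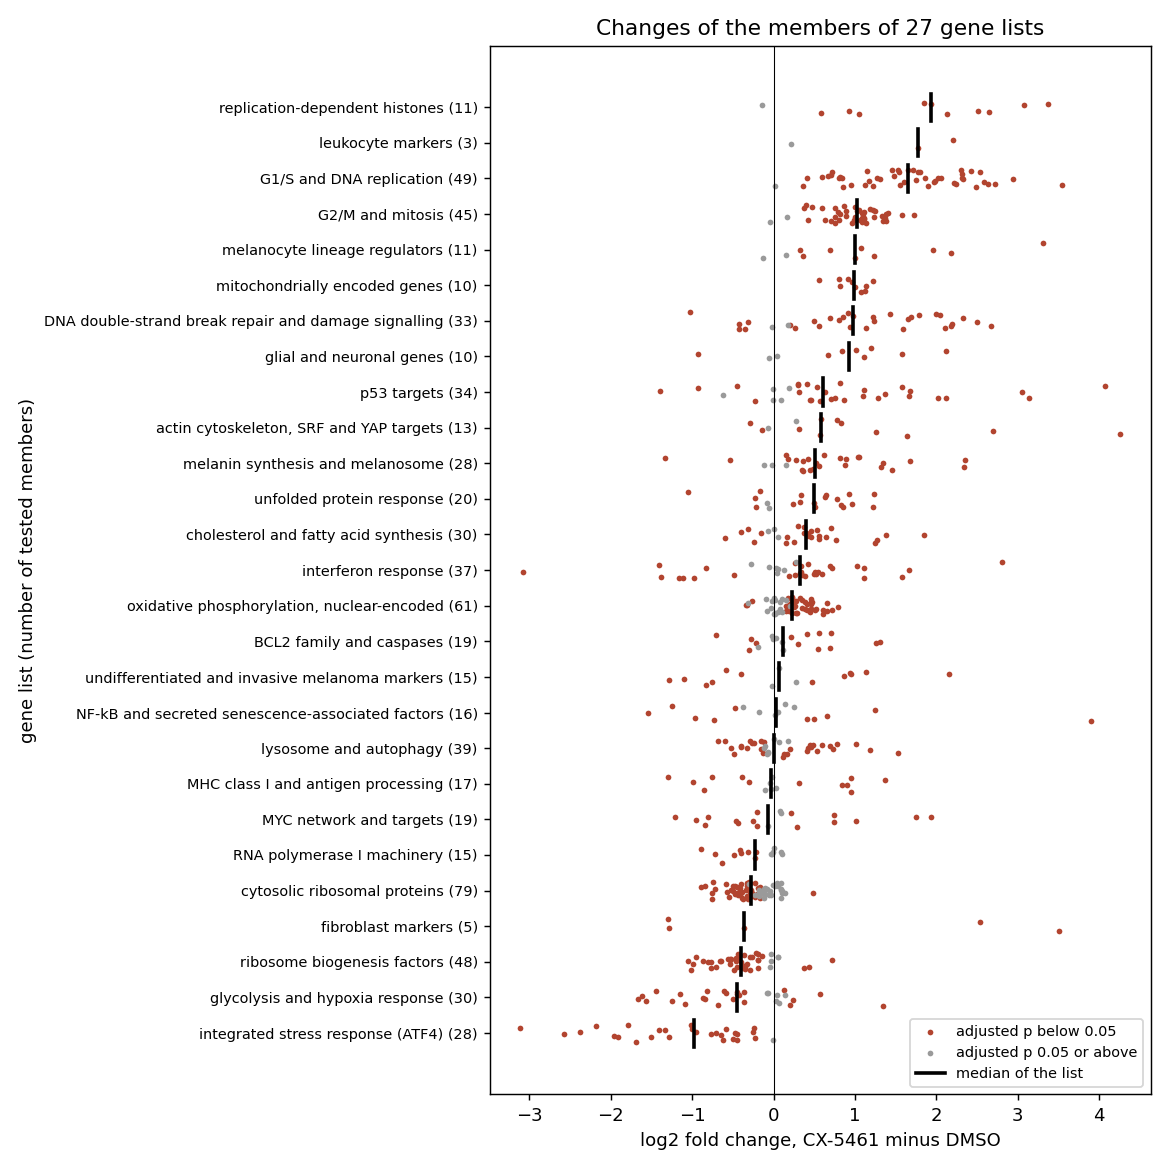
Log2 fold change, CX-5461 minus DMSO (horizontal axis), of each tested member of the 27 gene lists with at least 3 tested members (vertical axis, number of members in brackets). Red points passed an adjusted p below 0.05, grey points did not, and black bars mark medians, which ran from -0.98 for the ATF4 list to 1.94 for the histone genes.

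The lists of immune and secreted-factor genes did not pass camera, and their members went both ways. Of 37 interferon response genes, 22 rose, 8 fell and 7 did not pass, with a median of 0.33 (camera, adjusted p = 0.7494). The chemokine gene Cxcl10 fell 8.48-fold, whereas the mitochondrial nucleotide kinase gene Cmpk2 and the ISG15 protease gene Usp18 rose 3.17-fold and 2.98-fold. Of 17 genes of MHC class I and antigen processing, 6 rose, 6 fell and 5 did not pass (camera, adjusted p = 0.4782). The immunoproteasome subunit Psmb10 rose by 1.37 ± 0.09. This list had a median of -0.03 and a mean of 0.03, with camera in the lower direction. Of 37 NF-kB targets and secreted factors linked to senescence, only 16 had enough counts to be tested, and Il6, Il1b and Cxcl1 were among those left out. Of the 16, 5 rose, 5 fell and 6 did not pass (camera, adjusted p = 0.5638), so most of this list was not measured. Plau, urokinase, rose by 3.90 ± 0.23 from 0.336 ± 0.0512 CPM, while Vegfa and Relb changed by -1.25 ± 0.05 and -0.97 ± 0.06. The median of this list was 0.04 and its mean 0.10, and camera gave the lower direction.

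Cytoskeletal genes and markers of other cell types were also measured. Of 13 genes of the actin cytoskeleton and of SRF and YAP targets, 9 rose, 2 fell and 2 did not pass. The cytoplasmic actin gene Actg1, which has processed copies, rose 3.11-fold. The list passed camera (adjusted p = 0.01009), with adjusted p = 0.3752 with an estimated correlation. Of 10 glial and neuronal genes, 7 rose, 1 fell and 2 did not pass, and the GDNF receptor gene Gfra1 rose 4.33-fold, or 2.63-fold with the gene-span offset. That list passed camera (adjusted p = 0.01958), with adjusted p = 0.2737 with an estimated correlation, and did not pass with the gene-span offset (adjusted p = 0.06767, from 0.01153 over alternatives). Of 12 leukocyte markers 3 were tested, with a median log2 change of 1.77. Of these, 2 rose, both at least 2-fold, or 3 rose when adjusted over the list alone (camera, adjusted p = 0.4057). The 2 that rose had means below 5 CPM in both groups, so the median rests on genes with low counts. Cd68 was at 10.6 ± 0.153 and 12.3 ± 1.20 CPM (adjusted p = 0.06282). It passed without CX-5461 replicate 2 (0.28, adjusted p = 0.0185) and with the gene-span offset (0.33, adjusted p = 0.009894), with up to 0.2481 over alternatives. Of 5 fibroblast markers tested, 2 rose and 3 fell, and Col1a2, a chain of type I collagen, rose 11.4-fold to 25.1 ± 1.34 CPM. Their median was -0.37 while their mean, 0.62, and camera took the higher direction (adjusted p = 0.06412, and 0.03229 with the gene-span offset, with up to 0.09886 over alternatives). Cdh1 was the only epithelial marker tested and rose 2.32-fold, to 2.40 ± 0.269 CPM. Vwf was the only endothelial marker tested and rose 8.90-fold, to 29.7 ± 3.89 CPM.

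In total, 17 of 27 lists passed camera with its preset correlation, 13 higher and 4 lower, and 1 passed with the correlation estimated from these libraries. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.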

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

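The gene-span offset, and for the gene lists all settings but those fixed in advance for their number, were chosen after seeing the data. Under 20 alternatives the genes higher with CX-5461 numbered 3989 to 4818, those lower 3847 to 5109, those higher at least 2-fold 1221 to 1815 and those lower at least 2-fold 458 to 610, all within 1.5 times the reported counts. The extremes came from library totals only, no filter and an adjusted p of 0.01, and the 2-fold minima from the gene-span offset and the filter of 1 CPM. The gene lists past the set test numbered 15 to 17 under 17 settings of camera at the preset correlation, 23 with fry, which does not compare a list with other genes, and 1 with the correlation estimated. Of 77 genes taken by the rule, 72 kept their direction and call under each of the 19 settings that tested them. Top2b turned to -0.0483 with library totals only, to -0.0036 with the gene-span offset and without CX-5461 replicate 2, with -0.0352 to 0.0656 when single libraries were left out. Ubtf turned to 0.0993 with the gene-span offset and passed there as higher (edgeR, adjusted p = 0.04672). The test of the MYC list also turned with that offset, with a median of 0.0589, and did not pass (camera, adjusted p = 0.6887). The test of the undifferentiated and invasive melanoma markers turned without CX-5461 replicate 2, with medians from 0.0103 to 0.1315 when single libraries were left out. The causes were not tested. None of these genes lost its call, and 20 of 27 lists kept direction and call under all 17 settings.

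The labels do not say whether equal replicate numbers mark a shared culture or day. The deviations of same-numbered libraries from their group means correlated at 0.0364, 0.0037 and -0.0084. DMSO replicates 1 and 2 correlated best with their own number and DMSO replicate 3 with CX-5461 replicate 2, which is a hint from the data and not the design. With the number as a replicate block, 4536 genes were higher, 4464 lower, 1426 higher at least 2-fold and 508 lower at least 2-fold, and 17 lists passed. Levels under 3 counts, or 0.135 to 0.173 CPM, were not detectable at this depth. Few members of the histone, leukocyte, epithelial and endothelial lists had enough counts to be tested, and only 16 of 37 in the list of NF-kB targets and secreted factors. Why was not tested.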

Other observations

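The gene lists and genes named here, the gene-span offset, and the tests of GC content, expression level and scaling, were chosen after the main results had been seen. The other tests were chosen before their own values were seen. Of 18 heat shock response genes, 16 fell, 1 rose and 1 did not pass, with a median log2 change of -0.65 (camera, adjusted p = 9.225e-10, and adjusted p = 0.2301 with an estimated correlation). The small heat shock protein gene Hspb1 changed by -3.05 ± 0.11 (SE, n = 3 per group), from 31.0 ± 2.91 to 3.72 ± 0.0823 CPM (SD), and the inducible HSP70 gene Hspa1b by -2.23 ± 0.09. Of 8 genes of the cytosolic chaperonin, 7 fell and 1 did not pass (camera, adjusted p = 0.09777), where 5 fell and 1 rose with the gene-span offset, and of 31 proteasome genes 16 fell, 4 rose and 11 did not pass (adjusted p = 0.1374), where 10 fell and 8 rose with that offset. Of 20 NRF2 targets, 15 fell, 3 rose and 2 did not pass, with a median of -0.34 (camera, adjusted p = 0.0005276, and adjusted p = 0.315 with an estimated correlation). Heme oxygenase, Hmox1, fell 3.05-fold, from 5814 ± 82.9 to 1907 ± 100.8 CPM. The heat shock and NRF2 lists each shared 2 members with the preset lists. With the gene-span offset the median of the chaperonin list went from -0.25 to -0.13 and that of the proteasome list from -0.12 to -0.022. The medians of these lists had the same sign under 4 other scalings.

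Of 22 collagen genes tested, 16 rose, 4 fell (2 with the gene-span offset) and 2 did not pass, with a median of 1.38 (camera, adjusted p = 3.685e-05, and adjusted p = 0.2301 with an estimated correlation). The 2 chains of type I collagen parted, with Col1a2 at 3.51 ± 0.13 and Col1a1 at -1.30 ± 0.18 (log2, SE). Of 55 axon guidance receptors and ligands, 31 rose, 10 fell and 14 did not pass, with a median of 0.58 (camera, adjusted p = 0.0006989, and adjusted p = 0.315 with an estimated correlation). The call ended with the gene-span offset, where 28 of 54 members rose and 11 fell, with a median of 0.40 (camera, adjusted p = 0.05259, the highest of 5 alternatives, the lowest being 0.0003286). The ephrin receptor gene Epha3, which spans 320.6 kb, rose 5.61-fold, to 95.2 ± 4.33 CPM, and 2.83-fold with that offset. Both medians stayed above 0 under the 4 other scalings, and 3 collagens were also in the preset lists. Of the 37 interferon response genes tested, 22 rose and 8 fell. Among those that fell, Isg15, Ifit1, Rsad2 and Cxcl10 changed by -1.16 ± 0.07, -1.38 ± 0.08, -1.11 ± 0.06 and -3.08 ± 0.09, and among those that rose, Oas2, Cmpk2 and Usp18 changed by 2.81 ± 0.29, 1.67 ± 0.11 and 1.58 ± 0.16. In antigen presentation, H2-K1 changed by -0.99 ± 0.05 while Tap1, the peptide transporter, rose by 0.84 ± 0.09.

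The cell-cycle lists were higher while the ATF4 and hypoxia lists were lower, a pattern that might reflect cultures of DMSO cells that had stopped growing or run short of nutrients by day 3 as much as an action of CX-5461. The test of scaling decides nothing, since 4 other scalings moved the median of all genes by at most 0.0735, and the lowest median of the G1/S list over them was 1.58. A shortage of glucose with DMSO would place both Txnip and Arrdc4, which glucose induces, higher with CX-5461. Arrdc4 changed by -0.999 ± 0.116, against that prediction, while Txnip rose by 0.19 ± 0.06. Only these 2 genes were read and they parted, so a shortage of glucose is not settled. Growth arrest with DMSO cannot be told apart from the treatment, since 18 quiescence and FOXO targets went both ways (8 rose, 7 fell), with a median of -0.077 (0.0073 with the gene-span offset) while fry passed its threshold of 0.05 in the higher direction, and with Cdkn1b at -1.07 ± 0.05 and Fbxo32 at 1.37 ± 0.07. An effect of CX-5461 on the cycle stays open and was not tested apart from the groups.

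Long genes were higher. The median log2 change was -0.07 for 2909 genes that span up to 10 kb, 0.32 for 1033 genes of 100 to 200 kb, 0.97 for 408 genes of 200 to 400 kb and 1.71 for 149 genes over 400 kb (GRCm38). Of these 149, 137 rose, 4 fell and 112 were at least 2-fold higher, and genes over 100 kb made up 35.7% of the genes at least 2-fold higher and 13.1% of those tested. Across genes, which are not independent replicates, the Spearman correlation of change with span was 0.22.

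Genomic DNA in the CX-5461 libraries would raise silent genes too. Olfactory receptor genes were higher there, at 0.00082 to 0.00086 CPM per exonic kb against 0.00029 to 0.00055 in the DMSO libraries. But they gained only 8.3e-05 times as many CPM per exonic kb as the genes over 400 kb, and at most 0.000122 times over 9 pairs of libraries. Against GC content as the cause, the median of the long genes was still 1.67 with a GC offset. Low expression of long genes would give matched genes a like change, but the long genes lay 1.68 above the middle of 10000 lists matched on mean expression, of which the highest median was 0.36. With the gene-span offset the median of the long genes was 0.40, as that offset is made to remove the trend, and 7639 of the 8946 tested changes were still called in the same direction. An effect of CX-5461 on long genes, and a larger share of unspliced RNA, stay open and were not tested.

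The 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes or lists as reported. It gave 4538 higher, 4448 lower, 1430 higher at least 2-fold and 508 lower at least 2-fold, against at most 0 in any of the 9 other splits with edgeR, where 7 to 49 genes had an unadjusted p below 0.05. Each other split put libraries of both treatments in each group, so the treatment difference widened the spread and left almost no call possible. The 0 therefore decides nothing. The real split gave 17 lists past camera at the preset correlation, against 9 to 16 in the 9 other splits. Lists can thus pass that test without the real grouping. Yet each other split held unequal numbers of the treatments in its groups, so part of the treatment difference remained. These splits therefore cannot tell how many lists would pass with no treatment difference.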
